A study of Rattus norvegicus with 36 samples.

How the data were processed

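Small RNAs were sequenced from pieces of the descending thoracic aorta of male rats. The Dahl salt-sensitive strain (SS) was compared with 2 congenic strains that carry Brown Norway (BN) sequence on chromosome 2, the distal portion in S2Ba and the middle segment in S2Bb. Feeding of a normal-salt diet (NSD) or a high-salt diet (HSD, 4% NaCl) began at 4 to 6 weeks of age and ended at 12 to 13 weeks. Per the labels, RNA with an integrity number of at least 8 went into the libraries, 1 microgram of total RNA per animal, and single-end reads of 51 bp were collected with a target of 30 M reads per sample.

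The submitters' processing notes name bcl2fastq 1.8.4, FastQC, STAR 2.3.1, R 3.2.3 and edgeR 3.6.8. The role of each tool, the genome build, the microRNA annotation and the normalization are not given in the sources used here. The authors deposited 1 table of a normalized signal per microRNA and library, not log-transformed, with 835 names and 34 columns. In each column 100% of the values were whole multiples of 1 step (tolerance 1e-06), so whole reads were recovered by dividing by that step. The columns summed to 0.726 to 1.30 M, which corresponds to scaling factors of 0.768 to 1.38 on the total of the listed microRNAs. The signal is given in normalized reads per M reads (nRPM), where M stands for mega. Of the names, 576 follow miRBase and 259 have the form miR-n with a number, whose definition is not given in the sources used here.

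The labels describe 36 samples in 6 groups of 6. SS high-salt replicate 3 and S2Ba high-salt replicate 2 have no column in the table and were not analysed here. SS normal-salt replicate 1 and S2Ba normal-salt replicate 4 hold identical values for 100% of the names. Since 1 of those labels has to be wrong, both columns were left out, and 32 libraries were analysed. The labels name no batch, litter or pairing. The animal numbers in the sample titles go with diet. Normal-salt animals have lower numbers than high-salt animals, except that S2Bb high-salt replicates 2 and 3 have the lowest. An effect of number order cannot be told apart from diet in SS and S2Ba, and in S2Bb only those 2 replicates break the order. On normal salt S2Bb has the lowest numbers, so strain is affected likewise. The blocks of numbers used below lie within groups and cannot separate it.

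The comparisons, the model, the gene lists, the rule for naming microRNAs and most of the alternatives below were fixed before the data were examined. The filter and the pseudocount were set once the table was known to hold normalized values. MicroRNAs with at least 1 nRPM in at least 5 libraries were tested, 484 in all, of which 275 have a miRBase name and 209 a miR-n name. Values were transformed as log2(value + 1), a scale that understates the change of rare microRNAs. All 6 groups were fitted in 1 linear model with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance. Contrasts gave 7 pairwise comparisons and 2 differences of diet responses, and a call means a Benjamini-Hochberg adjusted p under 0.05 over the microRNAs tested. The plan named an edgeR test for counts and limma for normalized values. Because the deposited values are normalized, limma was used, and the edgeR test on recovered reads became an alternative, which made 4, 3 and 35 calls for diet in SS, S2Ba and S2Bb. Fold changes are differences between group means of these log2 values, with the SE from limma. They are therefore not the log2 ratios of the mean signals printed beside them.

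Gene lists covered smooth muscle, striated muscle, endothelium, red blood cells, white blood cells, fat, liver, neurons, epithelium, inflammation, fibrosis, hypoxia, the imprinted Dlk1-Dio3 cluster, the miR-17-92 family clusters, let-7 and the X-linked miR-322 cluster. A list of microRNAs with every precursor on chromosome 2 was taken from the reference annotation, which matched 274 of the 275 named microRNAs tested. The 13 lists with at least 3 tested members went through limma's camera with a preset correlation of 0.01, adjusted over 91 tests. Camera with an estimated correlation and fry were run beside it. Members were also counted after adjustment over the list alone. Chromosome 2 microRNAs were compared with the others by Fisher's exact test. Agreement between comparisons was measured by Pearson's and Spearman's correlation across microRNAs, which are not independent replicates.

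All called microRNAs of a comparison are named where there are at most 20. Above that, the rule takes up to 10 calls with the largest change in each direction among those with a mean of at least 10 nRPM over the libraries analysed. With no call, the 3 smallest p values are named. Each list contributes its 2 most abundant members and every member called over all microRNAs or over the list alone. Called chromosome 2 microRNAs and the 5 most abundant microRNAs complete the rule.

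Recovered depth ranged from 2.31 to 42.4 M reads per library, with a median of 19.4 M. Shares of reads in 1 library are given with an exact binomial 95% confidence interval, which covers counting error only, as does the floor of 3 reads, since PCR reads without molecular identifiers are not independent molecules. The procedure was tested on 10 simulated sets per diet comparison built from these libraries. A 2-fold change was called for 65.1% of the changed microRNAs in SS, 66.9% in S2Ba and 70.8% in S2Bb, and a 1.5-fold change for 30.4%, 31.3% and 37.7%. False calls made up 3.4%, 2.9% and 2.8% of all calls. Far more microRNAs were changed in these sets than were called in the data. In SS 655, 653 and 649 were changed by 1.5-, 2- and 4-fold over the 10 sets of 484 microRNAs. That makes the adjusted threshold easier to pass, so the rates may overstate recovery in the data. Each microRNA had 1 dispersion for all groups, so a wider spread in SS was not simulated. On the inflammation list, camera with the preset correlation gave an unadjusted p under 0.05 in 26% of 100 simulated sets with no shift, against 6% with an estimated correlation. That list was simulated alone, so the false-call rate after adjustment over all list tests was not measured.

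The alternatives fixed at that point were relative log expression (RLE) factors, total-read scaling, no filter, a stricter filter of 10 nRPM in 6 libraries, DESeq2 1.42.0, limma-voom with sample weights, a fit of the compared groups alone, robust empirical Bayes, limma-voom with runs of animal numbers as random blocks, and leaving out names with several precursors. After the data were seen, edgeR 4.0.16 on recovered reads, pseudocounts of 0.25 and 4, the identical library counted in either group and leave-one-out fits of every compared library were added.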

Results

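The series asks how salt and BN segments of chromosome 2 shape microRNAs of the rat aorta in a study of vascular inflammation. After the identical columns were left out, 5 SS, 5 S2Ba and 6 S2Bb libraries on normal salt and 5 SS, 5 S2Ba and 6 S2Bb libraries on high salt remained. Mean depth in M reads was 14.4 ± 4.57 (SD, n = 5) in SS, 19.4 ± 5.46 (SD, n = 5) in S2Ba and 27.2 ± 8.52 (SD, n = 6) in S2Bb on normal salt. On high salt it was 16.4 ± 8.43 (SD, n = 5) in SS, 17.7 ± 4.00 (SD, n = 5) in S2Ba and 20.1 ± 2.29 (SD, n = 6) in S2Bb. SS high-salt replicate 2 was the shallowest library with 2.31 M reads, and SS normal-salt replicate 6 followed with 6.56 M.

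**Figure D1:**
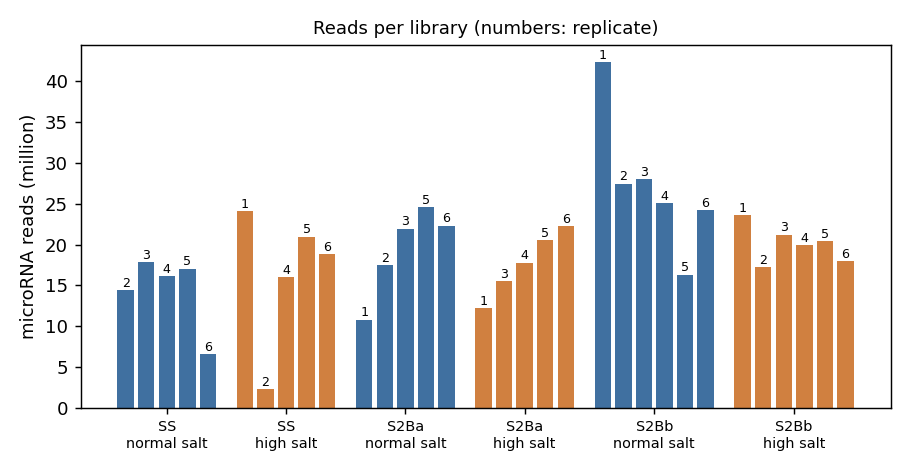
Recovered microRNA reads per library in M reads on a linear axis, with 1 bar per library, its replicate number above it and the bars ordered by the 6 groups of strain and diet. Depth runs from 2.31 M reads in SS high-salt replicate 2 to 42.4 M in an S2Bb normal-salt library.

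The aorta was dominated by miR-143-3p, the smooth muscle microRNA encoded beside miR-145, which held 54.0% of the normalized signal. It was followed by the Hox cluster microRNAs miR-10b-5p with 8.70% and miR-10a-5p with 7.31%, by miR-26a-5p with 4.51% and by miR-27b-3p with 4.01%. The other abundant smooth muscle member was miR-145-5p, with a mean of 4171 nRPM over the 32 libraries. In SS high-salt replicate 2, miR-143-3p took 31.7% of reads (exact binomial 95% confidence interval 31.6 to 31.7), against 42.6 to 60.0% in the other libraries, and 338 of 835 names were at 0. A count of 0 in that library allows up to 0.941 nRPM, the value of 3 reads.

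The other fixed groups were present at widely different levels, given as means over all libraries. Endothelial miR-126a-5p and miR-126a-3p, which lie in an intron of Egfl7, averaged 2167 and 242 nRPM. In the fibrosis list miR-199a-3p and miR-21-5p were the most abundant, at 4171 and 3043 nRPM, and in the inflammation list miR-21-5p was followed by miR-181b-5p at 1359 nRPM. The let-7 family, held back by Lin28 in early development, was led by let-7c-5p at 10545 and let-7f-5p at 8903 nRPM. Among white blood cell microRNAs, miR-146a-5p averaged 185 and miR-142-5p 83.6 nRPM, and among red blood cell microRNAs miR-451-5p averaged 11.8 and miR-144-3p 1.5 nRPM. Markers of other tissues included striated muscle miR-133a-3p at 603 and miR-133b-3p at 21.7, fat miR-378a-3p at 1224 and miR-365-3p at 83.2, and liver miR-192-5p at 465 and miR-194-5p at 32.4 nRPM. Neuronal miR-338-3p and miR-128-3p averaged 24.5 and 19, epithelial miR-205 and miR-141-3p 24.4 and 1.45, and hypoxia-induced miR-210-3p 21.8 nRPM. Cluster members were miR-127-3p at 297 and miR-434-3p at 58.1 for Dlk1-Dio3, miR-25-3p at 340 and miR-93-5p at 88.6 for miR-17-92, and miR-351-5p at 128 and miR-322-5p at 32.4 for the X-linked cluster. On chromosome 2, miR-16-5p averaged 2443 and miR-186-5p 537 nRPM.

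Libraries of 1 group correlated with r of 0.943 to 0.995 across microRNAs. The first principal components held 19.2%, 16% and 11.1% of the variance. On the first, SS high-salt replicate 2 stood apart with a score of 20.7, followed by SS normal-salt replicate 6 with 7.57. On the second, SS normal-salt replicate 2 and SS high-salt replicate 2 had the lowest scores, -10.6 and -10.5, and on the next SS normal-salt replicate 6 had the highest, 12.6. The median SD of log2 values within a group was 0.439 in SS on normal salt and 0.459 in SS on high salt, against 0.269 to 0.299 in the congenic groups.

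The diet comparison in SS asks what high salt does in the parental salt-sensitive strain. miR-199a-5p, a mesenchymal microRNA transcribed with miR-214, rose from 505 ± 112 (SD, n = 5) to 737 ± 33.6 (SD, n = 5) nRPM, and no library of 1 diet overlapped the other. miR-30b-3p, the less abundant arm of miR-30b, rose from 7.03 ± 3.28 to 18.2 ± 8.78 nRPM. miR-196b-5p, encoded in the Hoxa cluster, fell from 86.5 ± 81.3 to 13.4 ± 12.4 nRPM, with overlapping libraries. miR-n144 fell from 11.2 ± 2.57 to 5.23 ± 1.89 nRPM, and miR-n21 from 3610 ± 6602 to 36.8 ± 22.7 nRPM. The miR-n21 values on normal salt ran from 19.7 in replicate 2 to 15343 in replicate 6.

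In limma these were 5 calls in SS, 2 higher and 3 lower, and 90 microRNAs had an unadjusted p under 0.05. The log2 changes were 0.57 ± 0.13 (SE) for miR-199a-5p (adjusted p = 0.0308), 1.21 ± 0.30 for miR-30b-3p (adjusted p = 0.0410) and -2.22 ± 0.53 for miR-196b-5p (adjusted p = 0.0318). They were -1.0 ± 0.23 for miR-n144 (adjusted p = 0.0308) and -3.81 ± 0.98 for miR-n21 (adjusted p = 0.0481). All 8 let-7 members tested had a negative log2 change (7 under total-read scaling), and 4 of them fell when adjusted over the list alone, namely let-7a-5p (-0.55), let-7c-5p (-0.57), let-7f-5p (-0.72) and let-7i-5p (-0.42). The let-7 list passed camera (adjusted p = 0.000425) but not with an estimated correlation (adjusted p = 0.310). In the fat list, miR-196b-5p, miR-196a-5p (-1.36), miR-203a-3p (-0.76) and miR-203b-3p (-1.31) fell when adjusted over the list alone, and camera gave an adjusted p of 0.0297, against an adjusted p of 0.561 with an estimated correlation. The miR-196 members are Hox cluster microRNAs and miR-203 is abundant in epithelium, so these movers are not specific to fat. miR-192-5p fell by 0.52 in the liver list adjusted over the list alone. Each of the 5 calls was lost in at least 1 leave-one-out fit. Without normal-salt replicate 2, 3, 4, 5 or 6 limma made 1, 9, 0, 12 and 13 calls, and without high-salt replicate 1, 2, 4, 5 or 6 it made 0, 3, 11, 0 and 1. It also made 0 calls under total-read scaling (90 at an unadjusted p under 0.05), with only the compared groups fitted (31) and with the identical library counted as S2Ba (89), where DESeq2 made 20, edgeR 4 and limma-voom with sample weights 2.

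In S2Ba, high salt was compared with normal salt where the distal portion of chromosome 2 is BN. miR-132-3p, a CREB-induced microRNA, rose from 2.34 ± 0.945 (SD, n = 5) to 11.2 ± 7.55 (SD, n = 5) nRPM, with no overlap between libraries. miR-212-5p, processed from the same primary transcript, rose from 0.476 ± 0.273 to 2.13 ± 1.34 nRPM. miR-449a-5p, a relative of miR-34 encoded on chromosome 2, rose from 0.402 ± 0.316 to 1.38 ± 0.585 nRPM, with normal-salt replicate 6 at 0.956 and the others at 0.168 to 0.342. miR-n156 rose from 64.8 ± 11.1 to 122 ± 22.2 nRPM.

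These 4 calls were all higher on high salt, and 55 microRNAs had an unadjusted p under 0.05. The log2 changes were 1.70 ± 0.36 (SE) for miR-132-3p (adjusted p = 0.0147), 0.90 ± 0.19 for miR-n156 (adjusted p = 0.0147), 1.00 ± 0.25 for miR-212-5p (adjusted p = 0.0439) and 0.75 ± 0.19 for miR-449a-5p (adjusted p = 0.0439). Of 16 inflammation microRNAs tested, 6 rose and 0 fell when adjusted over the list alone. Besides miR-132-3p and miR-212-5p these were miR-212-3p (0.78), miR-146b-5p (0.71), miR-21-5p (0.71) and miR-34c-5p (0.74). As miR-132-3p and both miR-212 arms share a primary transcript, they are not separate observations, here or in S2Bb. miR-146b-5p is a relative of miR-146a, which targets Irak1 and Traf6, and miR-21-5p is induced in activated fibroblasts and immune cells. Camera called the list (adjusted p = 0.000163), but not with an estimated correlation (adjusted p = 0.251). The 4 white blood cell markers outside the inflammation list had a mean log2 change of 0.03 in S2Ba. In the miR-17-92 clusters, all 9 members tested had a positive log2 change (8 with RLE factors) and miR-17-5p (0.66) rose when adjusted over the list alone, with a camera adjusted p of 0.0159 and an estimated-correlation adjusted p of 0.522. All 7 members of the X-linked miR-322 cluster had a negative log2 change and 0 passed alone, with adjusted p of 0.00432 and, with an estimated correlation, adjusted p of 0.431. For Dlk1-Dio3, 15 of 18 were negative and 0 passed alone, with adjusted p of 0.0441 and 0.733 with an estimated correlation. On chromosome 2, miR-449a-5p and miR-92b-3p (1.03) rose when adjusted over the list alone, with adjusted p of 0.0449 and 0.251 with an estimated correlation. miR-143-5p (0.40) rose in the smooth muscle list when adjusted over the list alone, and miR-210-3p fell by 0.40, which passed without adjustment, as 1 member of the hypoxia list was tested (adjusted p = 0.210 over all microRNAs). Total-read scaling left 0 calls in S2Ba, where limma-voom with sample weights made 25, DESeq2 14 and edgeR 3. limma also made 0 calls without normal-salt replicate 2 or 5 or high-salt replicate 1, 3 or 4, but 7 without normal-salt replicate 1, 2 without normal-salt replicate 3 and 12 without high-salt replicate 5.

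In S2Bb, where the middle segment is BN, the diet comparison gave the largest number of calls. miR-138-5p, abundant in brain, rose from 3.34 ± 0.741 (SD, n = 6) to 19.6 ± 13 (SD, n = 6) nRPM. miR-146b-5p rose from 144 ± 37.6 to 262 ± 45.1 nRPM and miR-132-3p from 1.29 ± 0.657 to 5.79 ± 3.02 nRPM. miR-204-5p, encoded in an intron of Trpm3, fell from 439 ± 73.4 to 207 ± 34.8 nRPM. miR-145-5p, which maintains the contractile state of smooth muscle, fell from 4599 ± 809 to 2879 ± 583 nRPM, and the hypoxia microRNA miR-210-3p fell from 31.1 ± 2.79 to 19.2 ± 1.54 nRPM.

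limma made 29 calls in S2Bb, 12 higher and 17 lower on high salt, and 77 microRNAs had an unadjusted p under 0.05. Higher calls with a mean of at least 10 nRPM were miR-138-5p (log2 change 2.05 ± 0.37 SE, adjusted p = 0.00116), miR-30b-3p (1.09), miR-146b-5p (0.88, adjusted p = 0.00245), miR-30d-3p (0.82), miR-n156 (0.62) and miR-30d-5p (0.61). miR-30b and miR-30d come from 1 cluster of the miR-30 family. The 10 lower calls with the largest change at that level were miR-204-5p (-1.08 ± 0.19 SE, adjusted p = 0.00116), miR-152-5p (-1.01), miR-133b-3p (-0.89), miR-n266 (-0.71), miR-145-5p (-0.69), miR-210-3p (-0.67, adjusted p = 0.00194), miR-n260 (-0.65), miR-n178 (-0.65), miR-192-5p (-0.64) and miR-221-5p (-0.62). miR-n178 and miR-192-5p hold nearly equal values in every library, so they are not separate observations. Among the most abundant microRNAs, miR-26a-5p fell from 53095 ± 9803 to 35616 ± 7089 and miR-10a-5p from 93180 ± 14887 to 67553 ± 13859 nRPM, with adjusted p of 0.0304 and 0.0382. miR-211-5p, which shares its seed with miR-204-5p and was singled out after its values were seen, fell from 2.22 ± 0.235 to 0.961 ± 0.377 nRPM (adjusted p = 0.00320). It is far rarer than miR-204-5p, and whether reads of miR-204-5p were counted under its name was not tested. The 2 may therefore not be separate observations.

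**Figure D2:**
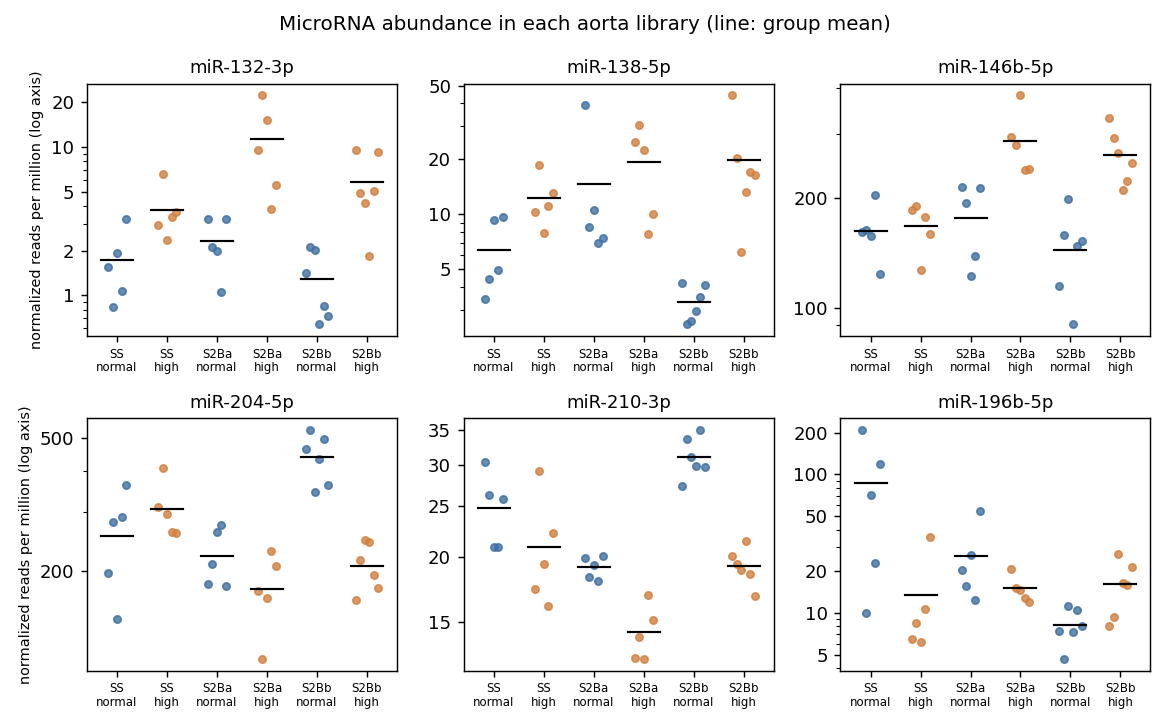
Normalized signal per library for named microRNAs in the 6 groups of strain and diet, on a log axis in normalized reads per M reads (nRPM), with 1 point per library and a bar at the group mean. miR-204-5p in S2Bb averages 439 nRPM on normal salt and 207 on high salt, and miR-132-3p averages 1.29 and 5.79.

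The inflammation list held 16 tested members, of which 5 rose and 2 fell over all microRNAs in S2Bb, and 7 rose and 3 fell when adjusted over the list alone. miR-132-3p (1.48, adjusted p = 0.00438), miR-212-5p (1.07), miR-212-3p (0.66) and the myeloid microRNA miR-223-3p (0.60) rose beside miR-146b-5p. miR-21-3p (1.26) and the p53 target miR-34a-5p (0.58) passed over the list alone. miR-31a-3p (-0.69), miR-31a-5p (-0.40, over the list alone) and miR-221-5p fell. In normal-salt replicate 5, miR-31a-3p stood at 18.7 nRPM, against 11.9 to 13.6 in the others. Camera called the list (adjusted p = 0.0350), but not with an estimated correlation (adjusted p = 0.522) and not without SS high-salt replicate 2 (adjusted p = 0.0559, with an estimated correlation 0.599). Endothelial miR-126a-5p rose from 1465 ± 436 to 2472 ± 388 nRPM when adjusted over the list alone, and miR-126a-3p was 274 ± 52.0 and 255 ± 47.2 nRPM. In their own lists, miR-145-5p fell for smooth muscle, miR-133b-3p for striated muscle, miR-192-5p for liver and miR-210-3p for hypoxia, while neuronal miR-128-3p (0.64) rose, each adjusted over the list alone. Adjusted over the miR-17-92 list alone, miR-17-5p (0.50) rose and miR-106b-3p (-0.51) fell, and camera did not call that list (adjusted p = 0.908). miR-92b-3p, a chromosome 2 microRNA, rose from 0.726 ± 0.260 to 3.16 ± 1.32 nRPM (log2 change 1.22, adjusted p = 0.00438).

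Of the 29 calls in S2Bb, 10 held in all leave-one-out fits and all alternatives that tested them, namely miR-138-5p, miR-132-3p, miR-212-5p, miR-92b-3p, miR-146b-5p, miR-30b-3p, miR-30d-3p, miR-30d-5p, miR-204-5p and miR-211-5p. The last 2 named may not be separate observations. Total-read scaling gave 12 calls, 9 higher and 3 lower, and there were 18 calls without normal-salt replicate 5, without high-salt replicate 2 or without high-salt replicate 4. Limma-voom with runs of animal numbers as random blocks gave 20 calls, and miR-145-5p and miR-10a-5p were among those lost.

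On normal salt, S2Ba was compared with SS for the effect of the distal BN portion. miR-194-5p, clustered with miR-192 in liver, kidney and gut, was higher in S2Ba, 51.1 ± 7.93 (SD, n = 5) against 27.8 ± 6.20 (SD, n = 5) nRPM, and libraries of the strains did not overlap. miR-1839-5p was lower, 14.5 ± 1.77 against 24.8 ± 5.12 nRPM. All 8 let-7 members were lower on average, and 5 passed when adjusted over the list alone, let-7a-5p (-0.64), let-7c-5p (-0.56), let-7d-5p (-0.40), let-7f-5p (-0.56) and miR-98-5p (-0.65). Let-7c-5p averaged 10036 ± 1436 nRPM in S2Ba and 15022 ± 3615 in SS.

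These were 2 calls in limma, with log2 differences of 0.87 ± 0.19 (SE) for miR-194-5p and -0.72 ± 0.16 for miR-1839-5p, both with adjusted p = 0.0242, and 73 microRNAs had an unadjusted p under 0.05. Camera called let-7 (adjusted p = 0.000129), but not with an estimated correlation (adjusted p = 0.251). miR-126a-5p (0.70) and miR-21-3p (1.40) were higher when adjusted over the endothelial and fibrosis lists alone. miR-210-3p (-0.35) was lower at an unadjusted p of 0.0188 (adjusted p = 0.207). limma made 0 calls without SS replicate 2 or S2Ba replicate 6, 9 without SS replicate 3, 4 without SS replicate 5, and 1 without SS replicate 6 or S2Ba replicate 1 or 5. Counting the identical library as S2Ba gave 0 calls and counting it as SS gave 7.

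S2Bb was compared with SS on normal salt for the effect of the middle BN segment. miR-196b-5p averaged 8.14 ± 2.37 (SD, n = 6) nRPM against 86.5 ± 81.3 (SD, n = 5) in SS, and miR-196a-5p 0.0622 ± 0.0750 against 4.27 ± 4.52. The S2Bb mean of miR-196a-5p lies below the value of 3 reads even in the deepest library, 0.0769 nRPM, so its log2 difference depends on the pseudocount. The far more abundant miR-10b-5p averaged 76818 ± 15926 against 141870 ± 46545 nRPM. miR-204-5p was higher in S2Bb, 439 ± 73.4 against 255 ± 85.4 nRPM. miR-10a-5p, also of a Hox cluster, was not called and averaged 93180 ± 14887 in S2Bb and 75047 ± 13747 in SS (log2 difference 0.32 ± 0.15 SE, adjusted p = 0.412). The ranges of the strains overlapped for all 4 calls.

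These 4 calls had log2 differences of -2.62 ± 0.51 (SE) for miR-196b-5p (adjusted p = 0.00597), -1.79 ± 0.40 for miR-196a-5p (adjusted p = 0.0260), -0.85 ± 0.20 for miR-10b-5p (adjusted p = 0.0284) and 0.84 ± 0.20 for miR-204-5p (adjusted p = 0.0284). At an unadjusted p under 0.05 there were 53. Of 8 let-7 members, all lower on average, 5 passed over the list alone, let-7a-5p (-0.39), let-7b-5p (-0.41), let-7c-5p (-0.52), let-7d-5p (-0.39) and let-7e-5p (-0.54), with a camera adjusted p of 0.000163 and an estimated-correlation adjusted p of 0.251. For Dlk1-Dio3, 16 of 18 members had a negative log2 difference and 0 passed alone, with a camera adjusted p of 0.0125 and an estimated-correlation adjusted p of 0.673. Members that passed over their list alone were miR-221-5p (0.70) for inflammation, miR-143-5p (0.43) for smooth muscle and miR-186-5p (0.56) for chromosome 2, all higher in S2Bb, as was miR-210-3p (0.32) at an unadjusted p of 0.0234 (adjusted p = 0.344). In the fat list the 2 members that passed were miR-196a-5p and miR-196b-5p. Limma-voom with sample weights gave 0 calls, edgeR 5 and DESeq2 15. Limma-voom with runs of animal numbers as random blocks, where the consensus correlation was 0.217, gave 0 (35 at an unadjusted p under 0.05), and so did limma with only the compared groups fitted (43). In these fits the miR-196b-5p difference was -2.18 ± 0.58 (SE), -2.66 ± 0.69 and -2.62 ± 0.59, so in the last 2 the SE grew while the difference did not shrink. In limma, only the miR-196b-5p call held in every leave-one-out fit. The count was 8 without SS replicate 3, 2 without SS replicate 2 or 6, and 1 without SS replicate 4 or S2Bb replicate 1 or 2.

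Deviations of miR-10a-5p from group means were compared with those of the 3 called Hox cluster microRNAs in the 27 libraries outside SS normal salt. For miR-196b-5p r was -0.253 and rho -0.216 (permutation p = 0.244 and 0.321, adjusted p = 0.244 and 0.366), and r was 0.00485 without the 2 libraries farthest from the median. For miR-196a-5p r was -0.376 and rho -0.427 (permutation p = 0.0789 and 0.0368, adjusted p = 0.148 and 0.110), and r was -0.466 without the 2 farthest. For miR-10b-5p r was 0.435 and rho 0.201 (permutation p = 0.0986 and 0.366, adjusted p = 0.148 and 0.366), and r was 0.101 without the 2 farthest.

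On high salt, S2Ba differed from SS by 1 call. miR-224-5p, encoded in an intron of Gabre, averaged 2.26 ± 0.936 (SD, n = 5) nRPM in S2Ba and 5.49 ± 1.57 (SD, n = 5) in SS, without overlap. Inflammation microRNAs stood higher in S2Ba, 7 of 16 when adjusted over the list alone, with miR-31a-5p (-0.36) lower. miR-21-5p averaged 4196 ± 1125 nRPM in S2Ba and 2470 ± 674 in SS, and miR-21-3p 39.96 ± 13.1 and 11.5 ± 3.2. The white blood cell microRNAs miR-142-5p (0.69), miR-142-3p (0.68) and miR-223-3p (0.47) were higher in S2Ba when adjusted over their list alone.

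The miR-224-5p difference was -1.01 ± 0.22 (SE) in log2 (adjusted p = 0.0317), and 82 microRNAs had an unadjusted p under 0.05. Besides miR-21-5p (0.78), miR-21-3p (1.69) and miR-223-3p, the higher inflammation members were miR-132-3p (1.18), miR-146b-5p (0.76), miR-212-5p (0.68) and miR-34a-5p (0.82). Camera gave adjusted p of 0.00698 for inflammation, 0.0350 for white blood cells and 0.00698 for miR-17-92, and with an estimated correlation an adjusted p of 0.477 for each. Dlk1-Dio3 had 16 of 18 members with a negative log2 difference and 0 past the threshold alone, with adjusted p of 0.000425 and 0.522 with an estimated correlation. In their lists alone, miR-17-5p (0.67), miR-19b-3p (0.84), miR-29a-5p (0.50), miR-449a-5p (0.69) and endothelial miR-126a-5p (0.87) were higher, and miR-133a-3p (-0.54) lower. miR-210-3p (-0.49) was lower at an unadjusted p of 0.00157 (adjusted p = 0.0846). limma made 0 calls without SS replicate 2, 4 or 5 or S2Ba replicate 3, 4 or 6, 10 without SS replicate 1 and 22 without S2Ba replicate 5. DESeq2 gave 31 calls, 17 higher and 14 lower. Total-read scaling, no filter and limma-voom with runs of animal numbers as random blocks each gave 0.

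For S2Bb against SS on high salt, limma made 0 calls, edgeR 0, limma-voom with sample weights 3 and DESeq2 2, while 56 microRNAs had an unadjusted p under 0.05. The smallest p values belonged to miR-223-3p (log2 difference 0.71, adjusted p = 0.260), miR-146b-5p (0.63, adjusted p = 0.300) and miR-664-3p (-0.72, adjusted p = 0.300), none past the threshold. miR-146b-5p averaged 262 ± 45.1 (SD, n = 6) nRPM in S2Bb and 168 ± 25.8 (SD, n = 5) in SS. Adjusted over the inflammation list alone, miR-146b-5p, miR-223-3p, miR-21-3p (1.17), miR-21-5p (0.63) and miR-212-5p (0.73) were higher and miR-31a-5p (-0.34) was lower, and the list's camera adjusted p was 0.133, or 0.00504 without SS replicate 2 (0.651 and 0.304 with an estimated correlation). In the fibrosis list alone, miR-214-3p (-0.81) and miR-30c-1-3p (-0.75) were lower and the miR-21 members higher. Endothelial miR-126a-5p (0.65) was higher over its list alone. Camera called miR-17-92, with 8 of 9 members positive and 0 past the threshold alone (adjusted p = 0.0396), and Dlk1-Dio3, with 15 of 18 negative and 0 past it alone (adjusted p = 0.00432). With an estimated correlation the adjusted p values were 0.523 and 0.617.

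Whether the diet response differs between strains was tested directly. The response of miR-204-5p differed between S2Bb and SS. It went from 439 ± 73.4 to 207 ± 34.8 nRPM in S2Bb (SD, n = 6) and from 255 ± 85.4 to 307 ± 60.5 in SS (SD, n = 5), a difference of -1.40 ± 0.28 (SE) in log2 (adjusted p = 0.0130). The response of miR-196b-5p also differed, from 8.14 ± 2.37 to 16.3 ± 7.08 in S2Bb and from 86.5 ± 81.3 to 13.4 ± 12.4 in SS, a difference of 3.07 ± 0.71 (adjusted p = 0.0369).

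These 2 calls were made in limma, with 46 at an unadjusted p under 0.05. The miR-204-5p difference held in each of the 22 leave-one-out fits and in all 15 alternatives. The miR-196b-5p call held in 7 of 22 leave-one-out fits and 9 of 15 alternatives. It was lost, leaving 1 call, without SS normal-salt replicate 2, 4 or 6, SS high-salt replicate 1, 2, 4 or 5, S2Bb normal-salt replicate 1, 2, 4 or 6, or S2Bb high-salt replicate 2, 3, 5 or 6. For S2Ba against SS, limma made 0 calls, edgeR 0, limma-voom with sample weights 0 and DESeq2 3, with 36 at an unadjusted p under 0.05. The smallest p values there were those of miR-n144 (1.00), miR-n215 (0.89) and miR-19b-3p (1.12), each with adjusted p = 0.620. SS high-salt replicate 2 held 4.39 nRPM of miR-19b-3p, against 9.66 to 13.1 in the other SS high-salt libraries.

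The strains differ from SS on chromosome 2, so its microRNAs were examined as a group. In the 4 strain comparisons, 0 of the 8 chromosome 2 microRNAs tested were called by limma, with too few calls among the others for a comparison. At an unadjusted p under 0.05 there were 0 in S2Ba and 1 in S2Bb on normal salt (miR-186-5p), and 3 in S2Ba (miR-449a-5p, miR-582-3p and miR-760-3p) and 2 in S2Bb (miR-449a-5p and miR-582-3p) on high salt. Fisher's exact test of these counts against the other named microRNAs gave p = 0.361 and 1 on normal salt and 0.398 and 0.364 on high salt. The ends of the BN segments are not given in the sources used here, so the whole chromosome was used.

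Red blood cell, fibrosis, neuronal, smooth muscle and striated muscle lists were not called by camera in any of the 7 pairwise comparisons, with smallest adjusted p of 0.223, 0.223, 0.126, 0.280 and 0.280. Without SS high-salt replicate 2, the only library left out of the list tests, neuronal in S2Bb against SS on high salt was called with the preset correlation (adjusted p = 0.0443) but not with an estimated one (adjusted p = 0.231). Endothelial, epithelial, liver and hypoxia lists had fewer than 3 tested members and no list test. miR-205 and miR-141-3p of the epithelial list did not pass over the list alone in limma. Over all lists, camera made 17 calls in 91 tests, 0 of which held with an estimated correlation. Fry made 8, among them let-7 for diet in SS (adjusted p = 0.0144) and in S2Ba (0.0144) and S2Bb (0.0198) against SS on normal salt. The others were inflammation (0.0144) and chromosome 2 (0.0144) for diet in S2Ba and neuronal (0.0198) for diet in S2Bb. Inflammation and miR-17-92 (0.0457 each) in S2Ba against SS on high salt completed them. Without SS high-salt replicate 2 camera made 18 calls, with 2 gained and 1 lost, and with an estimated correlation 0. The mean change of each of the 17 called lists kept its sign under RLE and total-read scaling. Median, mean and direction of the test differed in sign in 14 list tests, 0 of them called, with adjusted p of 0.452 or more. These were Dlk1-Dio3 and neuronal for diet in SS and striated muscle for diet in S2Bb (median 0.03, mean -0.11). On normal salt they were inflammation, miR-17-92, miR-322 and chromosome 2 in S2Bb against SS. On high salt they were fat, fibrosis (median -0.05, mean 0.19), neuronal and smooth muscle in S2Ba, and fibrosis, miR-322 and smooth muscle in S2Bb, each against SS.

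Diet responses were compared across strains over the 484 microRNAs. Pearson's r was 0.455 (jackknife SE 0.0819, rho 0.375) for SS and S2Ba, 0.348 (SE 0.164, rho 0.367) for SS and S2Bb, and 0.467 (SE 0.142, rho 0.412) for S2Ba and S2Bb. miR-132-3p, miR-212-5p and miR-n156 were called higher in both S2Ba and S2Bb, 3 shared calls against 0.0992 for independent sets. Since miR-132-3p and miR-212-5p share a primary transcript, they are not separate observations, and the expected number does not allow for that. miR-30b-3p was called higher in both SS and S2Bb, 1 against 0.155, and SS and S2Ba shared 0 against 0.0165. At an unadjusted p under 0.05, 13, 19 and 24 microRNAs went the same way in the 3 pairs and 0 went opposite ways, against 5.17, 7.17 and 4.56 shared for independent sets.

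**Figure D3:**
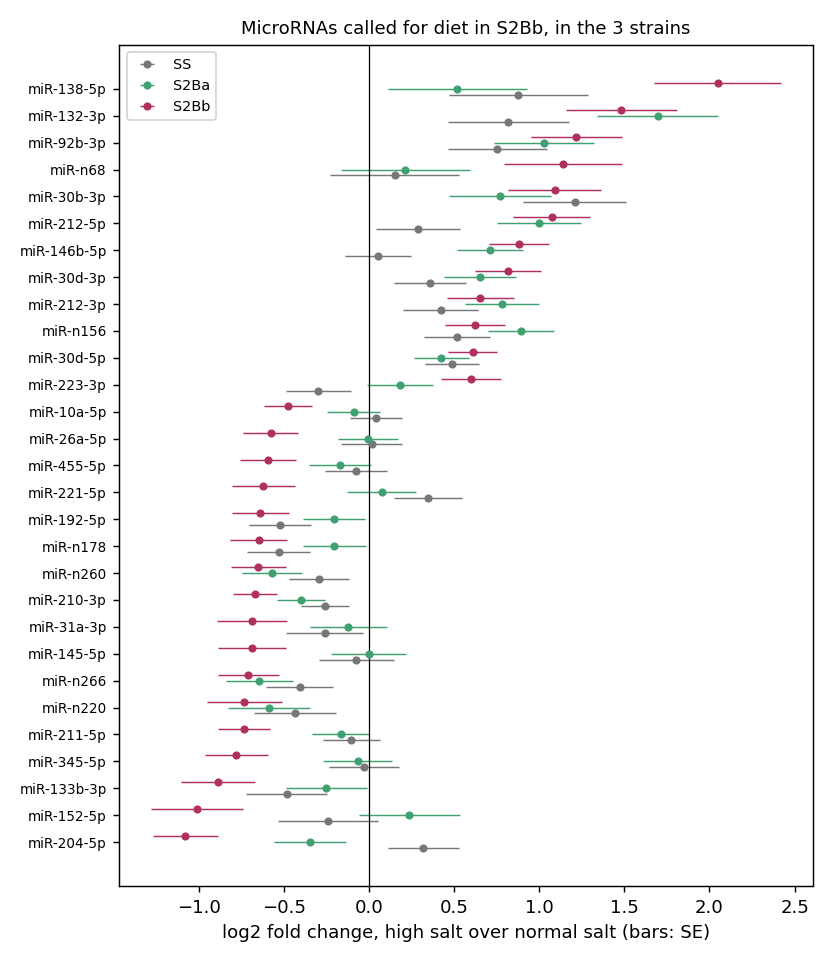
Log2 fold change of high over normal salt on the horizontal axis, with bars of 1 SE, for each microRNA called in the S2Bb diet comparison, with points for SS, S2Ba and S2Bb. Of the 29 microRNAs, 24 have the same sign in SS as in S2Bb and 27 do in S2Ba.

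Effects of the BN segments against the shared SS libraries correlated across microRNAs with r = 0.396 on normal salt and r = 0.625 on high salt. Simulated groups that did not differ from SS gave a median r of 0.532 and 0.524 through the shared libraries alone, with 95% of values from 0.125 to 0.818 and from 0.136 to 0.791. With the SS libraries divided between the comparisons, the median r over 20 divisions was -0.00089 on normal salt and 0.0891 on high salt. Over the 90 microRNAs with at least 100 nRPM, r was 0.620 on normal salt and 0.676 on high salt. Simulated groups gave medians of 0.563 and 0.539 there (95% of values from -0.132 to 0.865 and from -0.0727 to 0.862), and with the SS libraries divided the medians were 0.358 and 0.190. Neither set gave an r above the range that the shared SS libraries alone produced.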

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

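All tests of explanations in this part were chosen after the results they address were seen, except the splits of the libraries. The test of a response confined to S2Bb was rewritten and divided into parts after a first version over all 29 calls had been seen, which changed its outcome, and its counts of p values and mean changes were added later. In that version 24 calls had the same sign in SS (exact one-sided p = 0.0635) and 27 in S2Ba (p = 0.0556), and a response confined to S2Bb was not argued against.

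The diet response of miR-204-5p differed between S2Bb and SS by -1.40 in log2 (adjusted p = 0.0130), with lower values on high salt in S2Bb and a higher mean in SS. The diet response of miR-196b-5p differed between S2Bb and SS by 3.07 in log2 (adjusted p = 0.0369), and SS normal-salt libraries ran from 9.89 nRPM in replicate 3 to 210 in replicate 2. The miR-196b-5p call was lost in 15 of the 22 leave-one-out fits, in those without SS normal-salt replicate 2, 4 or 6, SS high-salt replicate 1, 2, 4 or 5, S2Bb normal-salt replicate 1, 2, 4 or 6 and S2Bb high-salt replicate 2, 3, 5 or 6, each of which left 1 call. miR-449a-5p in S2Ba on normal salt had a library apart from the others, replicate 6 with 0.956 nRPM against 0.168 to 0.342, a gap of 0.73 of the group's range. For miR-31a-3p in S2Bb on normal salt, replicate 5 held 18.7 nRPM against 11.9 to 13.6, a gap of 0.716 of the range. For miR-19b-3p in SS on high salt, the shallow replicate 2 held 4.39 nRPM against 9.66 to 13.1, a gap of 0.711 of the range. Of 110 groups of values examined, 3 had such a library, where chance gives about 1 in 20, or 5.5.

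The number of diet calls was 29 in S2Bb, 5 in SS and 4 in S2Ba, and with 5 against 5 S2Bb libraries the median in S2Bb was 17.5 calls over all 36 subsets, range 9 to 32, which argues against the number of libraries as the whole difference, though not as part of it. Among microRNAs with at least 100 nRPM limma made 8 calls in S2Bb, 2 in SS and 0 in S2Ba, or 10, 6 and 0 when adjusted over these microRNAs alone, which argues against deeper libraries resolving rare microRNAs as the whole difference, though not as part of that from SS. Of the S2Bb calls, 4 (miR-30b-3p, miR-132-3p, miR-212-5p and miR-n156) were also called in the same direction in another strain, and 8 of the other 25 (miR-146b-5p, miR-212-3p, miR-92b-3p, miR-30d-3p, miR-30d-5p, miR-210-3p, miR-n260 and miR-n266) passed in S2Ba in the same direction when adjusted over the 25 alone, 0 in SS, which argues against a response confined to S2Bb for those 8. For the 25 as a set a response confined to S2Bb and one shared with weaker effect cannot be told apart. The 25 were left after calls shared with another strain were taken out, so the set is biased against a shared response. In SS 20 had the same sign (exact one-sided p = 0.0794 over 252 splits) and in S2Ba 23 (p = 0.0595), against a median of 12 in other splits. The counts at an unadjusted p under 0.05 in a t test, 1 and 9, gave exact p of 0.353 and 0.0159. The mean changes in the S2Bb direction, 0.23 and 0.32, gave 0.0278 and 0.0238, and the smallest adjusted p over the 6 tests was 0.0556. The median SD within groups was 0.299 and 0.269 in S2Bb, below 0.439 and 0.459 in SS but close to 0.290 and 0.276 in S2Ba. Spread may therefore contribute to the gap from SS. Adjusted over all microRNAs, 1 of the 29 responses differed from that in SS, that of miR-204-5p. Its signs were opposite (-1.08 and 0.32, difference -1.40, adjusted p = 0.0130, the others 0.196 or more). That argues against an equal response in SS for miR-204-5p but not against a weak one in the same direction (SE 0.21 in SS). Adjustment over all microRNAs is stricter than that over the 25 alone, so this count cannot be set against the 8. Of the 29, 24 had the same sign in SS. Those with opposite signs included miR-221-5p (-0.62 in S2Bb, 0.35 in SS) and miR-223-3p (0.60 and -0.30), for which a differing response stays open. An effect of the middle BN segment stays open.

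miR-196b-5p, miR-196a-5p and miR-10b-5p, microRNAs of 3 Hox clusters whose expression varies along the body axis, were higher in SS than in S2Bb on normal salt. In the 27 libraries outside SS normal salt their deviations from group means had a mean correlation of 0.552, above 99.3% of 10000 random sets of 3 microRNAs, but with miR-10a-5p added it was 0.244, above 93.8% of random sets and short of the 95% set for a match, so a stretch of aorta sampled at varying levels may contribute for the 3 and is left open for Hox cluster microRNAs as a group. The pairs gave r = 0.770 and rho = 0.668 for miR-196b-5p and miR-196a-5p (permutation p = 5e-05 and 0.00085, adjusted 0.00015 and 0.00255). Whether these 2 miR-196 members are separate observations was not tested, and miR-196a-5p is near the floor. For miR-196b-5p and miR-10b-5p r was 0.534 and rho 0.570 (permutation p = 0.00044, adjusted 0.00066, for r). For miR-196a-5p and miR-10b-5p r was 0.352 and rho 0.214 (permutation p = 0.101 for r). Without the 2 libraries farthest from the median r was 0.648, 0.613 and 0.0638 in the order given, so the last relation rests on those libraries. With each SS library left out the upper 95% limits stayed at or below -1.14, -0.592 and -0.272, which argues against a single library, although the calls of miR-196a-5p and miR-10b-5p were lost without SS replicate 2, 4 or 6 (adjusted p up to 0.112). On high salt the miR-196b-5p difference was 0.458 (95% interval -0.57 to 1.49), which argues against a strain difference present on both diets for it, but for miR-196a-5p (0.00549, -0.817 to 0.828), which is near the floor, and miR-10b-5p (-0.280, -0.696 to 0.136) that cannot be told apart from a strain effect on normal salt alone, which stays open as untested.

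miR-132-3p rose on high salt in S2Ba and S2Bb, though the S2Ba call was lost without normal-salt replicate 2 or 5 or high-salt replicate 1, 3 or 4 (adjusted p from 0.000172 to 0.125 over leave-one-out fits and alternatives). The mean log2 change of the white blood cell markers miR-142-3p, miR-142-5p, miR-150-5p and miR-342-3p was 0.0269 in S2Ba (95% interval -0.286 to 0.340) and 0.127 in S2Bb (-0.159 to 0.412), which argues against a larger share of the white blood cells that carry these markers. They are the tested members outside the inflammation list. Of all 6 tested, 4 were positive in S2Ba (mean 0.03) and 5 in S2Bb (mean 0.27). The left-out myeloid miR-223-3p was called higher in S2Bb (0.60, 95% interval 0.244 to 0.959). Its interval overlaps that of miR-132-3p (0.820 to 2.14), so a larger share of myeloid cells stays open in S2Bb. The lower 95% limit of the miR-132-3p change was at least 0.779 over RLE and total-read scaling, which argues against scaling, although the S2Ba call was lost under total-read scaling (log2 change 1.71 against 1.70, adjusted p = 0.0734), against 0.0147 and 0.0154 with the deposited and RLE scaling. A response of the congenic strains alone stays open. The lower 95% limit of 0.0924 in SS (log2 change 0.82, adjusted p = 0.247) holds for this microRNA alone, without adjustment over those tested. Under total-read scaling it was 0.139, where the median of all microRNAs stood at 0.124. The differences of S2Ba and S2Bb from SS were 0.88 (adjusted p = 0.672) and 0.66 (adjusted p = 0.768). Their 95% intervals, -0.149 to 1.90 and -0.318 to 1.65, are too wide to decide between a shared and a congenic response. Activation of CREB in cells of the vessel wall may contribute and was not tested, nor was an influx of other cells.

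For each count of calls, 100 splits of the compared libraries, the real one included, were fitted. Fewer than 5 matching splits was the limit for each count, not adjusted over the 9 counts. The splits did not keep runs of animal numbers together (consensus correlation 0.217). At that limit chance can be excluded for diet in S2Bb, where 1 split gave as many as the real 29 and the highest other gave 2. Diet in S2Ba, where 3 gave as many as 4 and the highest other gave 7, also met the limit. So did the difference of diet responses between S2Bb and SS, where 4 gave as many as 2 and the highest other gave 9. Its splits exchanged strains within a diet. For these 2 counts chance is not called excluded, as they lie near an unadjusted limit. Chance cannot be excluded for diet in SS, where 14 splits gave as many as 5 and the highest other gave 43. It cannot be excluded on normal salt for S2Ba against SS, where 7 gave as many as 2 and the highest other gave 4, or for S2Bb against SS, where 5 gave as many as 4 and the highest other gave 10. It cannot be excluded on high salt for S2Ba against SS, where 8 gave as many as 1 and the highest other gave 16. The limma counts of 0 for S2Bb against SS on high salt (56 at an unadjusted p under 0.05, DESeq2 2, edgeR 0, limma-voom with weights 3) and for the difference of S2Ba and SS diet responses (36 unadjusted, DESeq2 3, edgeR 0, limma-voom with weights 0) are matched by all 100 splits, with highest others of 5 and 23. The SS split with 43 calls set normal-salt replicates 3 and 6 with high-salt replicates 1, 2 and 6 against the rest. These had the highest SS scores on the first principal component, led by 20.7 and 7.57 in the shallowest libraries. The split with 16 calls likewise set apart the highest scores, SS replicates 1 and 2 with S2Ba replicates 1, 3 and 4. So did the S2Ba diet split with 7 calls, normal-salt replicate 1 with high-salt replicates 1, 3, 4 and 6. Diet in S2Ba thus largely goes with this axis. The splits with 43, 16 and 9 calls against real counts of 5, 1 and 2, and with 23 against 0, point to a structure among the libraries. With 43 and 16 calls it follows the first component, and its cause was not tested. All splits given so far are a second draw, made after other permutations were added to the script. In the first draw 11 splits matched diet in SS (highest other 85) and 8 matched S2Bb against SS on normal salt (highest other 13). The highest others were 8 for diet in S2Bb, 11 for the difference of S2Bb and SS diet responses, 4 for S2Bb against SS on high salt and 1 for the difference of S2Ba and SS responses. The remaining values were equal, and whether a count met the limit was the same in both draws for every count.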

How the results depend on the processing

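The edgeR test on recovered reads, the other pseudocounts, the placements of the identical library and the leave-one-out fits were tests chosen after the data were seen. The 47 called results kept direction and call in 565 of 690 fits under the alternatives, lost the call in 125 and reversed in 0. Leaving out single libraries, they kept both in 367 of 556 fits, lost the call in 189 and reversed in 0. Robust empirical Bayes, edgeR and a pseudocount of 0.25 left every count within 1.5 times its value. Where counts moved, the cause was not tested.

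Total-read scaling gave 0 calls for diet in SS, 0 for diet in S2Ba, 12 for diet in S2Bb (9 higher, 3 lower), 1 for S2Ba against SS on normal salt and 0 on high salt. It moved the median of all microRNAs to 0.12 in the SS and S2Bb diet comparisons and in S2Ba against SS on normal salt. RLE factors gave 4 calls (3 higher, 1 lower) for S2Ba against SS on high salt.

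DESeq2 gave 20 calls for diet in SS, 14 in S2Ba and 41 in S2Bb. For strain it gave 18 (S2Ba) and 15 (S2Bb) on normal salt and 31 and 2 on high salt, and for the differences of diet responses 3 and 8. limma-voom with sample weights gave 2, 25 and 63 calls for diet in SS, S2Ba and S2Bb, 10 and 0 for strain on normal salt, 8 and 3 on high salt, and 4 for the difference of S2Bb and SS responses. Fitting the compared groups alone gave 0 calls for diet in SS, 0 for S2Ba and 0 for S2Bb against SS on normal salt, and 1 for the difference of S2Bb and SS responses. With limma-voom and runs of animal numbers as random blocks, a change of tool and of blocks together, the counts were 1 for diet in SS, 1 and 0 for S2Ba and S2Bb against SS on normal salt, 0 for S2Ba against SS on high salt and 1 for the difference of S2Bb and SS responses.

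Without a filter, S2Bb against SS on normal salt gave 1 call, S2Ba against SS on high salt 0, and the difference of S2Bb and SS responses 1. The stricter filter gave 1 call for diet in S2Ba, where rare called microRNAs were no longer tested, and 5 for S2Ba against SS on high salt. Leaving out names with several precursors gave 1 call for S2Ba against SS on normal salt. A pseudocount of 4 gave 6 calls for S2Ba against SS on high salt and 1 for the difference of S2Bb and SS responses. The identical library counted as SS gave 7 calls for S2Ba against SS on normal salt. Counted as S2Ba, it gave 0 there, 0 for diet in SS, 5 for S2Ba against SS on high salt and 1 for the difference of S2Bb and SS responses.

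Leaving out 1 library gave 0 to 13 calls for diet in SS, 0 to 12 in S2Ba and 18 to 31 in S2Bb. For strain it gave 0 to 9 (S2Ba) and 1 to 8 (S2Bb) on normal salt and 0 to 22 and 0 to 0 on high salt. For the differences of diet responses it gave 0 to 0 and 1 to 3.

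With an estimated correlation 0 list tests were called, also without SS high-salt replicate 2 (0, chosen after the data were seen), and with fry 8. At an unadjusted p under 0.05, 6 chromosome 2 results passed. Over microRNAs with at least 100 nRPM, r was 0.565, 0.354 and 0.556 for diet in SS and S2Ba, SS and S2Bb, and S2Ba and S2Bb, and 0.620 and 0.676 for the strain effects on normal and high salt. In SS high-salt replicate 2, 3 reads are worth 0.941 nRPM, which limits what that library shows of rare microRNAs.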

Other observations

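Tests of let-7 under other scalings and the search for equal values were chosen after the data were seen. The mean log2 change of the 8 let-7 members was -0.43 (95% interval -0.67 to -0.20) for diet in SS, -0.46 (-0.69 to -0.23) for S2Ba against SS and -0.38 (-0.60 to -0.16) for S2Bb against SS on normal salt. Under total-read scaling it was -0.24 (-0.55 to 0.07), -0.25 (-0.56 to 0.06) and -0.35 (-0.65 to -0.06), where the median of all microRNAs stood at 0.12, 0.12 and 0.03. With RLE factors it was -0.48, -0.44 and -0.37. All 3 comparisons use the SS normal-salt libraries, in which let-7c-5p averaged 15022 ± 3615 nRPM (SD, n = 5).

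Red blood cell microRNAs differed widely between animals of 1 group. miR-451-5p averaged 22.9 ± 29.4 nRPM (SD, n = 5) in S2Ba on high salt and 14.9 ± 21.8 (SD, n = 6) in S2Bb on normal salt. miR-n21 stood at 15343 nRPM in SS normal-salt replicate 6, 1893 in replicate 5 and 750 in replicate 4. In replicate 6, names of the miR-n form held 2.75% of reads, against 1.09 to 1.72% in the other analysed libraries.

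Some names carry the same values in every library. miR-378a-3p and miR-n146 were identical with a mean of 1224 nRPM, and miR-450a-5p and miR-n282 with a mean of 29, among 11 such sets, 5 of them tested. miR-n178 held 0.984 times the mean of miR-192-5p, so the 29 diet calls in S2Bb count nearly the same signal under both names.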
